A study of Mus musculus with 20 samples.

How the data were processed

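RNA from skeletal muscle of 20 mice was measured on 20 Affymetrix 3' expression arrays, 1 per mouse. Per the labels, total RNA was labelled with biotin. The titles and source names of the samples give 4 groups of 5 mice: untrained and trained wild-type mice (WT_untrained, WT_trained) and untrained and trained transgenic mice (TG_untrained, TG_trained). A free-text description that calls every sample transgenic and trained conflicts with these names and was not used for grouping. Single mice are named by their titles, in which WTUT and WTT stand for untrained and trained wild-type mice and TGUT and TGT for untrained and trained transgenic mice. The labels give no batch, array date, muscle, sex, age or training protocol.

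The deposited values are an intensity per probe set on a linear scale, from 0 to 19078, for 22690 probe sets. The authors had already scaled the arrays to each other, read from the values: the array medians lie between 157 and 175, that is from -0.04 to 0.07 log2 around their own median. The summary method, the scaling method and the reason for the 1745 empty cells (0.385% of the table) are not given in the sources used here. The table holds 59 zeros. Empty cells were treated as missing in the test of each probe set and filled with the mean of the group's other arrays for gene list tests only. For arrays no counting depth exists, and their number limits the precision.

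Values were used as deposited, without further scaling. Each was transformed to log2 after adding 66.7, the 20th percentile of the table. The 64 control probe sets were left out, and the remaining 22626 were filtered on their mean over all arrays, blind to group, at the 40th percentile (log2 7.59, about 126 in intensity), which left 13576. Of the 22626, 20380 carry exactly 1 gene symbol, 691 several and 1555 none. Symbols came from the platform's annotation and were looked up in a RefSeq gene table of assembly GRCm38.p6, where 20364 matched and 0 changed. The deposited table names no genome build, so no coordinates are given. Of the tested probe sets, 12467 carry 1 symbol and represent 8486 genes, and 906 have an empty cell.

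Differences were tested with limma 3.58.1 in R 4.3.3, with 4 group means in 1 linear model and moderated variances that follow a trend in mean level (16 residual and 3.47 prior degrees of freedom). The tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 13576 probe sets of each contrast, and a probe set is called past an adjusted p of 0.05. There were 7 contrasts: training in each genotype, the transgene in each training state, training averaged over genotypes, the transgene averaged over training, and their interaction. Gene symbols stand for 1 probe set, the brightest tested one. Fold changes are on the scale with the added constant, which shrinks changes of dim genes.

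Genes are named by a fixed rule. From each single contrast, it takes up to 10 higher and 10 lower genes with the largest change among those past the threshold, and from the averaged contrasts and the interaction up to 5 in each direction. Where fewer than 5 genes passed, it adds the 5 with the smallest p. It adds up to 2 higher and 2 lower passing members of each gene list, and always H2-K1, H2-D1, B2m, Tap1, Psmb8, Hspa5, Ddit3, Cd8a, Cd68, Myh3, Myh7, Myh2, Myh4, Ppargc1a, Pdk4, Cs and Vegfa. Sln, Sqstm1, Syvn1, Atp2a2 in the averaged contrast, Hspa1b and the clock and glucocorticoid genes outside these lists were named after their values were seen.

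Each contrast was also tested on 28 gene lists with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists. The same lists were tested with a correlation estimated from the residuals, and with fry, which asks whether a list's genes move one way on balance. A list score, the mean deviation of the members from their own mean over arrays, was compared by exact permutation. The 252 splits of 5 mice against 5 allow no two-sided p under 0.00794, and permutation within strata used 63504 splits. The grouping, the contrasts, the test, the filter, the constant, the lists, the naming rule and most alternatives were set before the data were examined. The permutation of list scores, the fits without the arrays or probe sets with empty cells, and a fit with the Gapdh 3' over 5' log2 ratio of each array as a covariate were chosen afterwards.

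The alternatives were quantile normalization, centring on array medians, an added constant of 1 or of the table's median, no filter, a filter at the 60th percentile, no variance trend, robust variance estimation, array weights, a fit to the compared groups alone, leaving out probe sets that can bind several transcripts, 1 probe set per gene, and leaving out each array in turn. The limma test was tested on simulated data in which 200 of 13576 probe sets were changed, in 20 simulations. For training in wild-type mice, 5 against 5, it found 44.5% of changes of 0.3 log2, 78.7% of 0.5 and 96.3% of 1, with 4.43% of calls false. For training averaged over genotypes it found 72.9% of changes of 0.3 log2 and 92.7% of 0.5, with 4.84% of calls false. The simulated noise was independent between probe sets, whereas real probe sets vary together between mice. Changes of 0.3, 0.5, 1 and 2 log2 were planted together, and the larger ones ease the adjusted threshold for the smaller. These rates may therefore not hold for the real arrays. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.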

Results

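Transcript levels in skeletal muscle were measured in 20 mice, 5 in each of 4 groups: untrained and trained wild-type mice, and untrained and trained transgenic mice that over-express MHC-I. The series asks how endurance training affects these transgenic mice. Each array gave between 21868 and 22686 probe set values. Median intensity per array ran from 157 to 175, and any pair of arrays correlated with r between 0.957 and 0.995. The first principal component held 32.4% of the variance between arrays and the second 19.9%. The Gapdh 3' over 5' log2 ratio, a reading of RNA integrity, averaged 0.01 in every group. The array of wild-type trained mouse wtt-137 has 822 empty cells and that of transgenic trained mouse TGT-133 has 386, so the trained groups hold the larger part of the missing values.

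Neither gene family that the abbreviation MHC-I can stand for was higher in transgenic mice. H2-K1, a heavy chain of the major histocompatibility complex class I, stood at 1102 ± 307 intensity (SD, n = 5) in untrained and 1222 ± 345 in trained wild-type mice, against 1069 ± 201 and 1067 ± 411 in transgenic mice. Averaged over training, the transgenic difference was -0.12 ± 0.15 log2 (SE) for H2-K1 (adjusted p = 0.724), -0.10 ± 0.16 for H2-D1 (adjusted p = 0.777) and 0.03 ± 0.12 for B2m, the light chain (adjusted p = 0.931). The probe sets used for H2-K1 and H2-D1 are of the kind that can bind several transcripts, so they may not be separate readings. Psmb8, an immunoproteasome subunit, differed by -0.03 ± 0.04 log2. Tap1, the peptide transporter of the class I pathway, was too dim to be tested. Myh7, the myosin heavy chain of slow (type I) fibres, was lower: 1254 ± 928 and 1259 ± 566 in wild-type mice against 473.5 ± 202 and 395 ± 75.4 in transgenic mice. It fell by 1.27 ± 0.26 on the log2 scale (adjusted p = 0.0201). The labels do not spell out the abbreviation or describe the construct, and whether these 3' probe sets would read the transgene's transcript is unknown, so the levels neither check nor contradict the genotype labels.

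**Figure D1:**
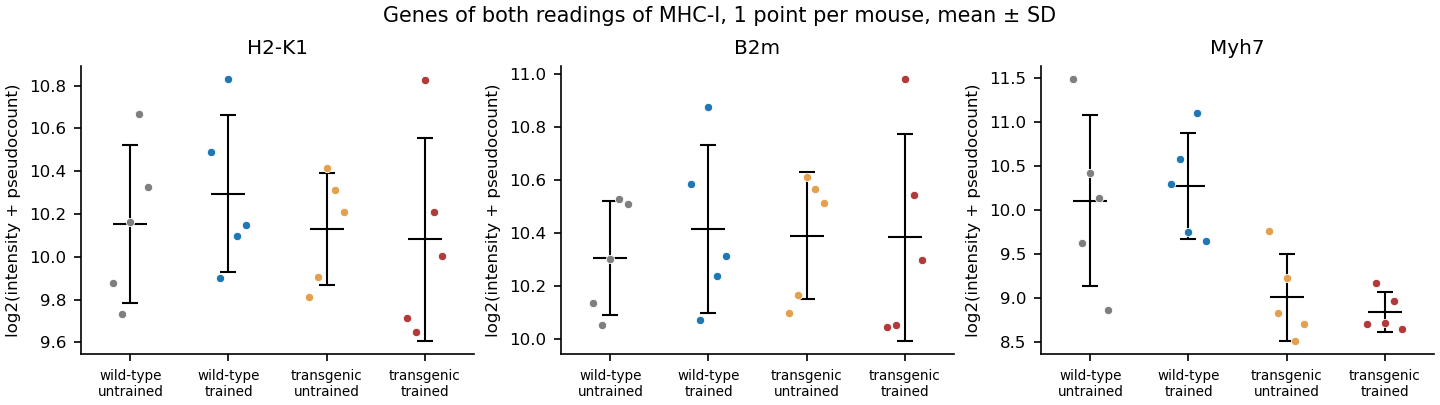
Log2 of intensity plus the added constant for H2-K1, B2m and Myh7 in each mouse by group, with group means and SD of these log2 values (5 mice per group). H2-K1 and B2m overlapped between genotypes. Before the log2 transform, mean Myh7 intensity was 473.5 and 395 in transgenic groups against 1254 and 1259 in wild-type groups.

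Transgenic muscle held less transcript of slow-fibre contractile genes, whether or not the mice had trained. Myl2, the regulatory light chain of slow myosin, stood at 1774 ± 1036 intensity (SD, n = 5) in untrained and 1805 ± 705 in trained wild-type mice, against 336 ± 215 and 250 ± 111 in transgenic mice. Averaged over training it fell by 2.38 ± 0.28 on the log2 scale, 5.21-fold (adjusted p = 0.00032). Tnni1, slow troponin I, fell by 1.51 ± 0.18 (2.85-fold, adjusted p = 0.00032), and Tnnt1, slow troponin T, by 1.99 ± 0.29 (3.96-fold, adjusted p = 0.00187). Every transgenic mouse lay below every wild-type mouse in Myl2 and in Tnni1. Atp2a2, the slow-twitch calcium pump, fell by 1.44 ± 0.22. Of the 11 measured slow fibre genes 8 fell, and 9 did so adjusted over the list alone. Their median was -1.11 log2 (camera adjusted p = 6.96e-17 at the preset correlation; adjusted p = 0.122 with an estimated correlation; exact permutation p = 6.3e-05, adjusted 0.00176). The 15 fast fibre genes had a median of 0.02 log2 (camera adjusted p = 0.126), and the fast myosin Myh4 differed by 0.02 ± 0.02.

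Csrp3 and Ankrd2 fell alongside them. Csrp3, the muscle LIM protein of the Z-disc, averaged 3713 ± 543 and 3599 ± 1197 intensity (SD, n = 5) in wild-type mice and 761 ± 631 and 1680 ± 494 in transgenic mice, and fell by 1.81 ± 0.29 on the log2 scale (adjusted p = 0.00357). Ankrd2, an ankyrin repeat protein induced by stretch and abundant in slow fibres, fell by 1.34 ± 0.19 (adjusted p = 0.0015). With Sln, the calcium pump inhibitor sarcolipin, they were the 3 of 19 muscle regeneration and embryonic muscle genes that fell (also 3 adjusted over the list alone). The median of the list was only -0.07 log2 (camera adjusted p = 0.026; adjusted p = 0.59 with an estimated correlation; exact permutation p = 0.00123, adjusted 0.0115), and the camera call was lost without TGUT-147 (adjusted p = 0.053), wtt-134 (0.067), wtt-137 (0.13), WTUT-136 (0.082) or WTUT-142 (0.064).

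The heat shock list was lower in transgenic mice averaged over training at camera's preset correlation. Of 16 measured, 3 fell (15 adjusted over the list alone): Bag3, a co-chaperone of filamin turnover, by 0.47 ± 0.09 on the log2 scale (adjusted p = 0.0141), Hsph1 by 0.39 ± 0.07 (adjusted p = 0.0131) and Hspa8, the constitutive Hsp70, by 0.20. The list's median was -0.43 log2 (camera adjusted p = 3.02e-11; adjusted p = 0.15 with an estimated correlation; exact permutation p = 0.00728, adjusted 0.0509). In trained mice alone the median was -0.20 (0 of 16 called; camera adjusted p = 0.00502, a call lost without wtt-134 (0.055) or wtt-137 (0.089); adjusted p = 0.751 with an estimated correlation; exact permutation p = 0.254, adjusted 0.497), and 4 of 16 had values above 0 under quantile normalization. The difference between training states had an exact permutation p of 0.0767. Aldh1a1, a retinaldehyde dehydrogenase, rose by 0.64 ± 0.10 log2 (1.56-fold, adjusted p = 0.00358), Slc2a3, a glucose transporter, by 0.42 ± 0.08 (adjusted p = 0.0138), and Tef, a clock-controlled transcription factor, by 0.34 ± 0.06 (adjusted p = 0.00581). Ighm, the immunoglobulin M heavy chain, fell by 0.72 ± 0.13 (adjusted p = 0.0125).

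Averaged over training, limma called 167 probe sets for the transgene, 44 higher and 123 lower. Under quantile normalization the split was 113 higher and 121 lower. The count was 79 without WTT-141, 83 without TGT-143, 90 without TGT-128 or TGUT-146, 96 without WTUT-135, 100 without WTT-129 or WTUT-142, 103 without TGT-132 or WTT-144, 336 without TGUT-147 and 525 without wtt-137. It was 399 without both arrays with the most empty cells. Myl2, Tnni1, Tnnt1, Myh7, Csrp3, Ankrd2, Bag3, Hsph1, Aldh1a1, Slc2a3, Tef and Ighm were called in each of the 20 fits with 1 array left out. Other called genes had log2 values of 0.44 for Ogn, 0.41 for Ctsc, 0.36 for Car14, 0.32 for Nr4a2, -1.48 for Acss1, -0.51 for Thbs4 and -0.33 for Atf4, with calls that held in 15, 7, 5, 13, 10, 3 and 7 of those fits.

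In untrained mice alone, Phlda3 and Pdgfa had the smallest adjusted p for the transgene, and slow fibre genes were among those called. Csrp3 fell by 2.56 ± 0.40 on the log2 scale (adjusted p = 0.0171), Myl2 fell by 2.20 ± 0.39 (adjusted p = 0.0272), Ankrd2 by 1.64 ± 0.27 (adjusted p = 0.0258) and Tnni1 by 1.28 ± 0.25 (adjusted p = 0.048). Phlda3, a p53 target that restrains Akt, fell from 1150 ± 275 intensity (SD, n = 5) to 454 ± 106, by 1.22 ± 0.17 (adjusted p = 0.00796). Pdgfa, a growth factor for connective tissue cells, fell by 0.61 ± 0.09 (adjusted p = 0.00796) and Tnfrsf12a, the TWEAK receptor, by 0.94 ± 0.18 (adjusted p = 0.0368). Hspa8 fell by 0.35 ± 0.06 (adjusted p = 0.0258), and Olfm1 and Xpo1 had log2 values of -0.52 and -0.50. Tef rose by 0.47 ± 0.08 (adjusted p = 0.0258). The slow fibre list had a median of -0.95 log2 (2 of 11 fell, 9 adjusted over the list alone; camera adjusted p = 6.29e-15; adjusted p = 0.0991 with an estimated correlation; exact permutation p = 0.0159, adjusted 0.148). The heat shock list had a median of -0.51 (1 of 16 fell, 11 adjusted over the list alone; camera adjusted p = 5.35e-18; adjusted p = 0.0533 with an estimated correlation; exact permutation p = 0.0159, adjusted 0.148). In all, 15 probe sets of 13 genes were called, 2 higher and 13 lower (5 and 14 under quantile normalization). The count was 2 without TGUT-139, WTUT-135 or WTUT-138, 6 without TGUT-131 or TGUT-146, 7 without WTUT-136, 8 without WTUT-130, 24 without TGUT-147 and 26 without TGUT-145. Of the 10 fits with 1 of these arrays left out, Phlda3 and Pdgfa were called in each, Csrp3 in 7, Myl2, Ankrd2, Tef, Tnfrsf12a and Olfm1 in 4, Hspa8 and Xpo1 in 3 and Tnni1 in 2. A limma fit to the compared groups alone called 0 probe sets (899 at an unadjusted p under 0.05), with Phlda3 and Pdgfa at an adjusted p of 0.182.

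In trained mice, slow fibre genes were among the genes called for the transgene. Myl2 fell by 2.57 ± 0.39 on the log2 scale (5.92-fold, adjusted p = 0.0104), Tnnt1 fell by 2.28 ± 0.41 (adjusted p = 0.0444) and Tnni1 fell by 1.74 ± 0.25 (adjusted p = 0.00678). Enc1, an actin-binding protein known from neurons, fell from 491 ± 30.5 intensity (SD, n = 5) to 142.1 ± 37.3, by 1.43 ± 0.19 (adjusted p = 0.00535). The slow fibre list had a median of -1.27 log2 (3 of 11 fell, 9 adjusted over the list alone; camera adjusted p = 3.77e-15; adjusted p = 0.177 with an estimated correlation; exact permutation p = 0.00794, the smallest possible, adjusted 0.111). Adipocyte markers had a median of -0.41 here (0 of 13 called; camera adjusted p = 0.00509; adjusted p = 0.751 with an estimated correlation), a call lost without TGT-128 (0.055), TGT-132 (0.088), WTT-129 (0.10) or wtt-137 (0.090). Their difference between training states was -0.29 (camera adjusted p = 0.166). In all, 7 probe sets of 6 genes were called, 0 of them higher, and 1692 had an unadjusted p under 0.05. The count was 2 without TGT-133, TGT-143 or WTT-141, 3 without TGT-128, 4 without WTT-129 or wtt-134, and about 1.4e+02 (13 higher and 90.8% lower) without wtt-137, with Tnni1 and Enc1 called in each of these 10 fits, Myl2 in 7 and Tnnt1 in 2. A fit to the compared groups alone called 26.

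**Figure D2:**
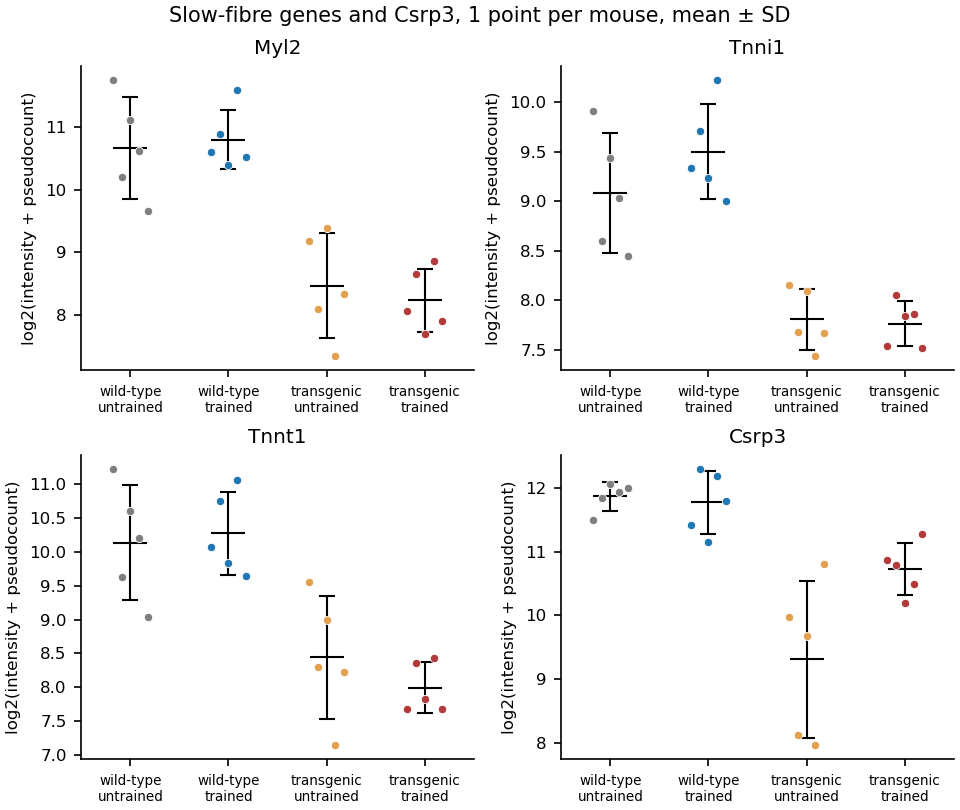
Log2 of intensity plus the added constant for Myl2, Tnni1, Tnnt1 and Csrp3 in each mouse by group, with group means and SD of these log2 values (5 mice per group). Before the log2 transform, mean Myl2 intensity was 1774 and 1805 in untrained and trained wild-type mice and 336 and 250 in transgenic mice.

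Training raised transcripts of the mitochondrial respiratory chain, by small amounts across many genes. Averaged over genotypes, Ndufb10, a subunit of complex I, rose by 0.39 ± 0.06 log2, 1.31-fold (adjusted p = 0.00297). It stood at 2464 ± 212 intensity (SD, n = 5) in untrained and 3195 ± 117 in trained wild-type mice, and at 2338 ± 214 and 3118 ± 361 in transgenic mice. Atp5g1, a subunit of ATP synthase, rose by 0.36 ± 0.05 (adjusted p = 0.00297). Of 46 oxidative phosphorylation genes 22 rose, 40 adjusted over the list alone, and 45 had values above 0. Their median was 0.15 log2 (camera adjusted p = 7.1e-24; adjusted p = 0.555 with an estimated correlation; exact permutation p = 0.000157, adjusted 0.00441). With arrays centred on their medians the median was the same to 2 decimals and 10 rose. With a score of clock activator minus clock output genes as a covariate, chosen after the data were seen, the median was 0.14 with a median SE of 0.06 against 0.04, and limma called 0 of the 22 (28 of 46 at an unadjusted p under 0.05); the score itself differed by -0.64 with training (exact permutation p = 0.00183). In the tricarboxylic acid cycle list, 7 of 20 genes rose, 14 adjusted over the list alone. Among them were 2 that act outside the cycle itself: Dlat of the pyruvate dehydrogenase complex, by 0.45 ± 0.10 log2 (adjusted p = 0.0205), and Mdh1, cytosolic malate dehydrogenase, by 0.30 ± 0.05 (adjusted p = 0.00651). Of the cycle's own enzymes, citrate synthase Cs rose by 0.14 ± 0.04 (adjusted p = 0.0341, called in 9 of the 20 fits with 1 array left out). That list's median was 0.14 (camera adjusted p = 9.49e-10; adjusted p = 0.598 with an estimated correlation; exact permutation p = 0.000787, adjusted 0.011). Esrra, a nuclear receptor that drives mitochondrial genes, rose by 0.24 ± 0.05 (adjusted p = 0.0173), and Sod2, the mitochondrial superoxide dismutase, by 0.28 ± 0.05 (adjusted p = 0.00926). Ppargc1a, the coactivator of these genes, differed by 0.17 ± 0.26 log2 (adjusted p = 0.796), with group means of 1110 and 991 intensity in untrained and trained wild-type mice and 715 and 792 in transgenic mice, and had no stable direction (lowest value -0.015 with 1 array left out).

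Casq2 and Myh1 rose and Mylk2 fell with training, while the slow fibre list was not called (median 0.00 log2, camera adjusted p = 0.587). Casq2, the calcium store protein of slow and cardiac muscle, rose by 0.36 ± 0.06 log2 (adjusted p = 0.00421), and Myh1, the myosin of type IIx fibres, by 0.21 ± 0.05 (adjusted p = 0.0303; called in 15 of the 20 fits with 1 array left out). The probe sets used for Casq2 and Myh1 are of the kind that can bind several transcripts. The Myh1 value may therefore not read that myosin alone. Mylk2, the skeletal myosin light chain kinase, fell by 0.52 ± 0.08 on the log2 scale (adjusted p = 0.003). Myh7 differed by 0.00 ± 0.26 log2, Myh2, the type IIa myosin, by 0.36 ± 0.17 (adjusted p = 0.219) and Myh4 by 0.01, none past the threshold. Atp1b1, a sodium pump subunit, rose by 0.65 ± 0.15 (adjusted p = 0.0206). Col3a1, a fibrillar collagen, rose by 1.02 ± 0.28 (adjusted p = 0.04) and Tfrc, the transferrin receptor, by 0.99 ± 0.28 (adjusted p = 0.0479), calls that held in 6 and 5 of the 20 fits with 1 array left out.

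Cdkn1a and single genes of protein breakdown and fatty acid handling fell with training. Cdkn1a, the cell cycle inhibitor p21, fell by 1.13 ± 0.25 on the log2 scale (adjusted p = 0.0164). Of 22 protein breakdown and atrophy genes 3 fell and 1 rose, while adjusted over the list alone 19 fell and 1 rose. Foxo3, a transcription factor of atrophy genes, fell by 0.52 ± 0.14 (adjusted p = 0.0427), Eif4ebp1, a repressor of translation, by 0.60 ± 0.17 (adjusted p = 0.0436) and the autophagy receptor Sqstm1 by 0.42; the calls of Foxo3 and Eif4ebp1 held in 8 and 6 of the 20 fits with 1 array left out. Map1lc3a, an autophagosome protein, rose by 0.25 ± 0.06 (adjusted p = 0.0182). The list's median was -0.45 log2 (camera adjusted p = 3.99e-09; adjusted p = 0.704 with an estimated correlation; exact permutation p = 0.0119, adjusted 0.111). Within groups, the protein breakdown score followed that of 8 genes known to respond to glucocorticoids and fasting (r = 0.949), chosen after the data were seen. That score differed by -0.38 with training (exact permutation p = 0.0157, adjusted 0.0556). A different glucocorticoid or fasting state at sampling can thus not be told apart from training for this list. The protein breakdown score also followed the first principal component within groups (r = 0.932). The same limit may therefore reach other genes that fell with training, such as Cdkn1a, which was not tested gene by gene. Ucp3, an uncoupling protein induced by fatty acids, fell by 0.54 ± 0.15 (adjusted p = 0.047) and the thioesterase Acot2 by 0.44 ± 0.10 (adjusted p = 0.0225), the 2 of 24 fatty acid genes that passed, with calls that held in 5 and 19 of the 20 fits. Pdk4, a kinase that inhibits the pyruvate dehydrogenase complex, had a difference of -0.69 ± 0.21 (adjusted p = 0.0594). Among 30 genes of the unfolded protein response 3 fell, Xbp1 by 0.41 ± 0.12, Atf4 by 0.28 ± 0.08 (called in 4 and 8 of the 20 fits) and Syvn1 by 0.20, and the list was not called (median 0.00, camera adjusted p = 0.587).

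Averaged over genotypes, limma called 678 probe sets for training, 327 higher and 351 lower, of 521 genes. The split was 485 higher and 360 lower under quantile normalization and 203 and 206 with arrays centred on their medians. Without both arrays with the most empty cells, which lie in the trained groups, the count was 409. With 1 array left out it was 279 without TGT-128, 280 without TGT-140, 298 without WTUT-135, 313 and 316 without TGUT-139 and TGUT-131, 337 without wtt-137, 387 without WTUT-142, 414, 421 and 439 without WTT-129, WTUT-130 and wtt-134, and 1285 without TGUT-145. Atp5g1, Ndufb10, Mdh1, Dlat, Sod2, Esrra, Casq2, Mylk2, Atp1b1, Cdkn1a and Map1lc3a were called in each of the 20 fits. Other called genes had log2 values of 0.61 for Trp53inp2, 0.60 for Mybph and 0.14 for Mpeg1, and of -0.95 for Tbc1d15, -0.92 for Snhg1, -0.84 for Arntl, -0.79 for Htra1, -0.53 for Cldn5, -0.51 for Plin4 and -0.30 for Phkb and Fbp2. Their calls held in 12, 9, 2, 11, 7, 17, 19, 10, 9, 7 and 10 of those fits.

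In wild-type mice alone no gene passed the threshold for training. Casq2 stood at 216 ± 30.6 intensity (SD, n = 5) in untrained and 310 ± 29.7 in trained mice, a difference of 0.42 ± 0.08 log2 (adjusted p = 0.145). Alas1, the first enzyme of heme synthesis, differed by 0.52 ± 0.10 (adjusted p = 0.145), Mylk2 by -0.54 ± 0.11, Slc25a11, a mitochondrial carrier of 2-oxoglutarate and malate, by 0.37 ± 0.07 (both adjusted p = 0.165), and Gnas by -0.15 ± 0.03 (adjusted p = 0.181). Of the oxidative phosphorylation genes 45 of 46 had values above 0, with a median of 0.13 log2 (0 rose, 5 adjusted over the list alone; camera adjusted p = 4.06e-19; adjusted p = 0.634 with an estimated correlation; exact permutation p = 0.00794, the smallest possible, adjusted 0.148; 0.0317 under quantile normalization and 0.0238 with arrays centred on their medians, before adjustment). Macrophage and dendritic cell markers had a median of 0.06 log2 and extracellular matrix genes of 0.15 (camera adjusted p = 0.00305 for each; adjusted p = 0.634 and 0.882 with an estimated correlation). The score of wtt-137, the array with the most empty cells, was the highest of the trained wild-type mice in both lists (0.19 and 0.31), and without it the medians were 0.04 and 0.11 (camera adjusted p = 0.0215 and 0.0254). Protein breakdown genes had a median of -0.25 (camera adjusted p = 0.00376; adjusted p = 0.907 with an estimated correlation), a call lost without wtt-134 (0.059), wtt-137 (0.65) or WTUT-142 (0.19). Limma called 0 probe sets, with 1069 at an unadjusted p under 0.05 where chance gives about 679, and limma with array weights called 92. Without WTT-144 the count was 4.

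In transgenic mice, training raised single genes of the respiratory chain and lowered, among others, Htra1 and Acvr1b. Ppif, cyclophilin D of the mitochondrial permeability pore, rose from 451.5 ± 90 to 830 ± 178 intensity (SD, n = 5), by 0.79 ± 0.15 log2 (adjusted p = 0.0404). Spr, sepiapterin reductase of tetrahydrobiopterin synthesis, rose by 0.47 ± 0.07 (adjusted p = 0.00773). Ndufb10 rose by 0.40 ± 0.08, Atp5g1 by 0.40 ± 0.07, Ndufa8 of complex I by 0.38 ± 0.08 and the mitochondrial ribosomal protein Mrps12 by 0.39 ± 0.07. Htra1, a secreted protease, fell from 1769 ± 714 to 617 ± 88.9 intensity, by 1.33 ± 0.27 on the log2 scale (adjusted p = 0.0453). In untrained and trained wild-type mice Htra1 averaged 809 and 676, and Acvr1b 784 and 754, against 1107 and 461 for Acvr1b in transgenic mice. For both genes the untrained transgenic mean was thus the highest of the 4 groups. Acvr1b, an activin and myostatin receptor, fell by 1.09 ± 0.22, Ets2 by 0.86 ± 0.17, Gpt2, the mitochondrial alanine transaminase, by 0.71 ± 0.14 and the kinase Jak1 by 0.58 ± 0.12. Other called genes had log2 values of 0.46 for Cmc2, 0.35 for Adamtsl5, 0.29 for Hspa4l and 0.28 for Ptcd2, and of -0.81 for Tle4, -0.61 for 2610005L07Rik, -0.53 for Art3, -0.49 for Nek7 and -0.48 for Fntb. All 46 oxidative phosphorylation genes had values above 0, with a median of 0.17 (3 rose, 30 adjusted over the list alone; camera adjusted p = 1.36e-20; adjusted p = 0.629 with an estimated correlation; exact permutation p = 0.0238, adjusted 0.267). With arrays centred on their medians 0 rose (exact permutation p = 0.0635), and under quantile normalization 9 rose (exact permutation p = 0.0159). The protein breakdown list had a median of -0.65 (0 of 22 called, 15 fell adjusted over the list alone; camera adjusted p = 1.29e-11; adjusted p = 0.629 with an estimated correlation; exact permutation p = 0.0238, adjusted 0.267). In all, 42 probe sets of 32 genes were called, 18 higher and 24 lower. The split was 93 higher and 60 lower under quantile normalization and 2 and 9 with arrays centred on their medians. The count was 2 without TGT-128 or TGT-140 or TGUT-131 or TGUT-139, 3 without TGUT-147, 6 and 7 without TGT-143 and TGT-132, 278 without TGUT-146 and 764 without TGUT-145. Spr was called in each of these 10 fits, Adamtsl5 and Art3 in 4, Ppif, Ndufb10, Atp5g1, Ndufa8, Mrps12, Htra1, Gpt2, Cmc2 and Fntb in 3 and the other named genes in 2. A fit to the compared groups alone called 1 probe set, and Spr then had an adjusted p of 0.0643.

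**Figure D3:**
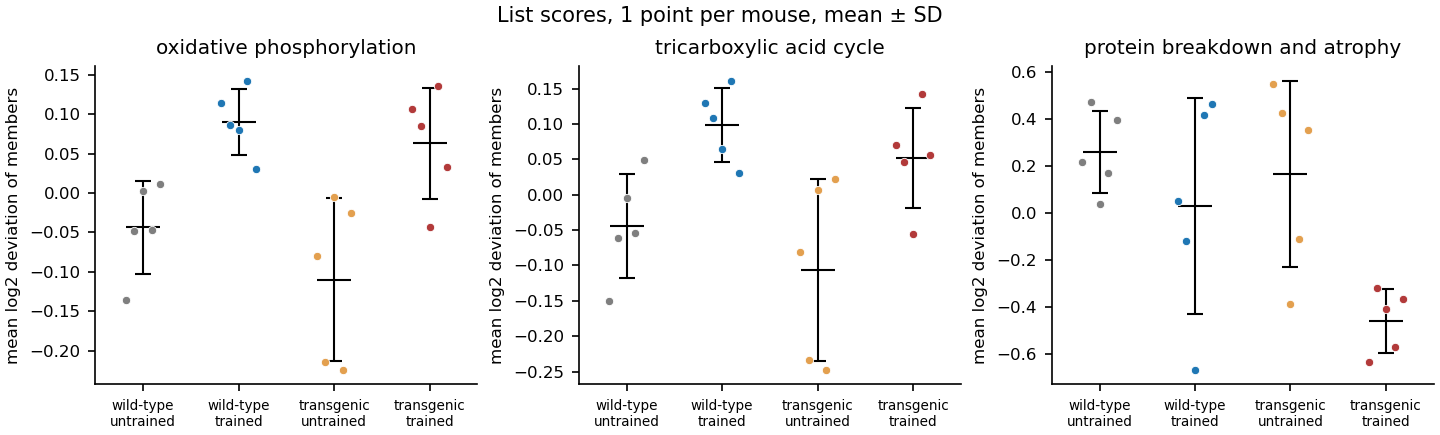
Mean log2 deviation of the members of 3 gene lists in each mouse by group, with group means and SD (5 mice per group). The oxidative phosphorylation score averaged -0.04 and 0.09 in untrained and trained wild-type mice and -0.11 and 0.06 in transgenic mice.

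The training response was not shown to differ between genotypes. At camera's preset correlation 6 gene lists were called for the interaction, against 0 with an estimated correlation, with fry or by exact permutation. Limma called 0 probe sets for the interaction, with 395 at an unadjusted p under 0.05 where chance gives about 679, and limma with array weights called 7. The smallest p belonged to Lox, the enzyme that cross-links collagen, with -0.89 ± 0.20 log2, Serping1, the C1 inhibitor, with -0.61 ± 0.14, Eif5 with -0.52 ± 0.13, Spr with 0.35 ± 0.09 and Tm7sf2, a sterol reductase, with 0.32 ± 0.08, each at an adjusted p of 0.9999. Across the 13576 probe sets, the training changes of the genotypes correlated with r = 0.506, a correlation across genes, which are not independent replicates. Of the 42 probe sets called in transgenic mice, 40 had the same sign in wild-type mice and 19 an unadjusted p under 0.05 there, with a median size of 0.18 log2 against 0.46. The transgene differences of untrained and trained mice correlated with r = 0.527, and the 15 and 7 called probe sets all had the same sign in the other training state, with 2 called in both.

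**Figure D4:**
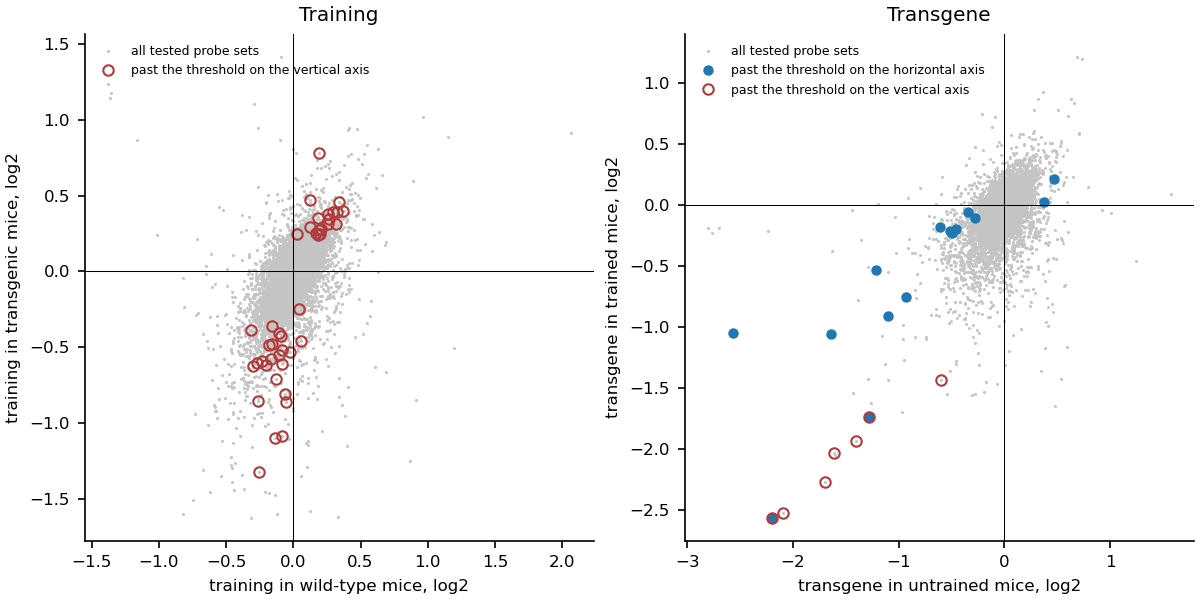
Log2 change of each tested probe set for training in wild-type against transgenic mice, and for the transgene in untrained against trained mice, with called probe sets marked. The changes correlated with r = 0.506 and r = 0.527.

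Averaged over training, camera called no transgene difference in the immune and unfolded protein response lists. The medians were 0.00 log2 for 10 MHC class I and antigen processing genes (camera adjusted p = 0.953), 0.05 for 17 interferon genes (0.131), -0.03 for 30 unfolded protein response genes (0.229) 0.07 for 9 T cell markers (0.0563; called without TGT-143 (0.043), TGUT-145 (0.029) or WTUT-138 (0.045)), 0.10 for 4 MHC class II genes (0.198), 0.03 for 10 NF-kB targets and inflammatory cytokines (0.953), -0.0038 for 18 macrophage and dendritic cell markers (0.953), 0.05 for 7 neutrophil markers (0.439) and -0.0048 for 3 B cell and plasma cell markers (0.272). The score of the B cell and plasma cell list was lower by exact permutation (-0.23, p = 0.000504, adjusted 0.00705), with Ighm the 1 member called. The mean and the camera direction of the class I list were below 0 while its median was above. Hspa5, the main chaperone of the endoplasmic reticulum, differed by -0.11 ± 0.08 (adjusted p = 0.51) and Ddit3 by -0.03 ± 0.05. Cd8a differed by 0.12 ± 0.07 (adjusted p = 0.402) and Vegfa by -0.12 ± 0.05 (adjusted p = 0.221), while Cd68 and Myh3 were too dim to be tested. Adipocyte markers had a median of -0.28 (0 of 13 called, 2 fell adjusted over the list alone; camera adjusted p = 0.0117), endothelial markers of -0.08 (1 of 15, Cdh5, fell, 2 adjusted over the list alone; camera adjusted p = 0.0461) and fatty acid genes of -0.13 (0 of 24 called; camera adjusted p = 0.000281), with adjusted p = 0.591, 0.482 and 0.591 with an estimated correlation. Protein breakdown genes had a median of -0.26 (0 of 22 called; camera adjusted p = 6.33e-05; adjusted p = 0.59 with an estimated correlation; exact permutation p = 0.068) and exercise-responsive regulators of -0.15 (1 of 26 rose; camera adjusted p = 0.0446). The camera calls of the adipocyte, endothelial and exercise-responsive lists were lost on leaving out any of several single arrays, for example without WTUT-142 (adjusted p = 0.057, 0.06 and 0.16). Oxidative phosphorylation had a transgene median of -0.04 (camera adjusted p = 0.000976; adjusted p = 0.639 with an estimated correlation), which turned to 0.03 under quantile normalization. With an estimated correlation, camera called 0 of the 28 lists in each of the 7 contrasts.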

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

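The tests with the Gapdh 3' over 5' ratio, the clock score and the glucocorticoid and fasting score were chosen only after the result was seen. So were the fit without both arrays with the most empty cells and the permutation of list scores.

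Of 516 sets of values of 1 group examined, 20 had a value that stood apart from the others by more than Dixon's limit for that number of mice, where chance gives about 26. Empty cells made up 3.62% of the values of wtt-137 (at most 0.141% in the others of its group), 1.70% of TGT-133 (at most 0.0926%) and 0.582% of WTUT-142 (at most 0.123%). The median intensity of TGT-133 was 174.9 (160.5 to 163.9 in the others). Among list scores, wtt-137 stood at 0.19 for macrophage and dendritic cell markers, WTT-141 at -0.22 for exercise-responsive regulators, TGT-132 at -0.11 for circadian clock genes and TGUT-139 at -0.34 for muscle regeneration and embryonic muscle genes.

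Among named genes, the log2 level of the clock gene Arntl was 7.64 in TGUT-145 (8.33 to 8.54 in the others) and that of Lox 8.59 in the same mouse (9.16 to 9.31). Tfrc reached 10.70 in wtt-137 (8.60 to 9.13), and Gnas 12.64 there and 12.72 in TGUT-145. In TGT-132, Myh2 stood at 12.29 and Hspa4l at 7.91, and in TGT-133 Ets2 stood at 8.72. Fbp2 was at 7.77 and Ppif at 9.41 in WTT-144, Spr at 8.37 in WTT-129 and Art3 at 10.06 in WTUT-138.

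The training response of 6 gene lists differed between genotypes at camera's preset correlation. The difference (transgenic minus wild-type) was -0.32 log2 for protein breakdown and atrophy (adjusted p = 8.84e-07), 0.25 for heat shock proteins (1.94e-06), -0.092 for extracellular matrix (0.0023), 0.042 for oxidative phosphorylation (0.013), 0.10 for fatty acid uptake and oxidation (0.0271) and -0.037 for macrophage and dendritic cell markers (0.0326). None of the 6 held with an estimated correlation, where each had an adjusted p of 0.769 or 0.772, and exact permutation p ran from 0.0767 for heat shock proteins to 0.692 for oxidative phosphorylation. Without wtt-137 the extracellular matrix median was 0.01.

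For each contrast, 100 splits of the same arrays were drawn, the real one included. At a limit of 5% of the splits, not corrected over the 7 contrasts, 5 of the 7 counts were rarer than the limit. The transgene in untrained mice was so only narrowly, with 4 of the 100 giving as many. Few splits were drawn and some others gave far more calls. Chance is thus made less likely for these counts but is not excluded. For training in transgenic mice (42 probe sets) 2 splits gave as many and the highest other gave 1954; for the transgene in untrained mice (15) it was 4 and 2230; in trained mice (7) it was 2 and 64. For training averaged over genotypes (678), 1 split gave as many, the real one, and the highest other gave 554. For the transgene averaged over training (167), it was 2 and 202. For training in wild-type mice and for the interaction the real count is 0 (limma, 1069 and 395 probe sets at an unadjusted p under 0.05; 92 and 7 called with array weights), which all 100 splits meet by construction, so the splits say nothing on chance there (highest others 192 and 1). The splits that called 1954 and 2230 probe sets, many times the real counts, point to a structure among the mice other than genotype and training.

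Slow fibre genes were lower in transgenic mice, with a median of -1.11 log2. Without both arrays with the most empty cells it was -1.15, with 8 of the 8 called members still called, so those arrays do not carry it. With the Gapdh ratio as a covariate, which moved the count of called probe sets from 167 to 464, the median was -1.10 with 8 of 8 still called, and the 95% limits of the ratio's difference (0.00241 between genotypes) and of the score's slope on it allow a shift of at most 0.27 in a score difference of -1.03, which argues against RNA quality as read by that ratio as the whole cause. Within groups, the members varied together between mice with a median r of 0.67, so a different share of slow muscle in the sampled tissue could also give the difference and cannot be told apart from a lower level per fibre, since the labels do not name the muscle. The transgene itself, the biological difference the design names, stays open alongside it.

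Oxidative phosphorylation genes were higher after training, with a median of 0.15 log2. Under quantile normalization it was 0.14 (exact permutation p = 0.000252) and with arrays centred on their medians 0.15 (exact permutation p = 0.00217), which argues against the scaling between arrays for the list as a whole, although with centring 10 members rose and not 22, as the median SE went from 0.04 to 0.05. With the Gapdh ratio as a covariate, which moved the count of called probe sets from 678 to 1292, it was 0.14 with 22 of 22 still called, and the 95% limits of the ratio's difference (-0.00402 with training) and of the score's slope on it allow a shift of at most 0.07 in a score difference of 0.15 (46.3%), which argues against RNA quality as read by that ratio as the whole cause, though not as a part of it. With a clock score as a covariate the median was 0.14 but 0 of 22 calls were left by limma (28 of 46 members at an unadjusted p under 0.05), because the median SE rose from 0.04 to 0.06, and the clock score differed between trained and untrained mice (-0.64, exact permutation p = 0.00183), so a different clock time at sampling may contribute and cannot be told apart from training by these calls. The clock score was chosen after the data were seen, and the preset circadian clock list was not called for training. Whether clock time differed is thus itself uncertain. Training itself, the difference the design names, stays open.

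Protein breakdown genes differed between mice of the same group. Their score correlated within groups with that of 8 genes known to respond to glucocorticoids and fasting (Fkbp5, Sgk1, Klf9, Zbtb16, Lpin1, Irs2, Pik3r1 and Sesn1) with r = 0.949 and rho = 0.914 over 20 mice (permutation p = 1e-05 for each, the smallest possible, adjusted 1.5e-05 over 3 relations; r = 0.897 without the 2 mice farthest out), and 8 of 10000 random lists of 8 genes matched on level did as well. The Gapdh ratio correlated with r = -0.144 and rho = -0.0782 (permutation p = 0.612 and 0.777; 95% interval of r from -0.584 to 0.362; r = 0.22 without the 2 farthest), an interval too wide to exclude RNA quality as read by it. A candidate explanation is a glucocorticoid or fasting state that varied between mice at sampling, but Klf15, Cebpd, Tsc22d3, Ddit4, Mt1 and Mt2 of the protein breakdown list are themselves known glucocorticoid targets, and 4 of 27 other lists also had an absolute r above 0.5. The random lists had a median absolute r of 0.346 and a 95th percentile of 0.792. A moderate r with the protein breakdown score is thus common among genes drawn at random by level, while one as large as 0.949 was rare. That rarity does not tell a glucocorticoid or fasting state from another difference that moves the same genes. The score followed the first principal component (r = 0.932, rho = 0.935, permutation p = 1e-05 for each; r = 0.917 without the 2 farthest), so it marks the main difference between mice.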

How the results depend on the processing

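Leaving out the probe sets with an empty cell or both arrays with the most empty cells, the Gapdh covariate and the permutation of list scores were chosen only after the result was seen. No paired analysis was possible because every mouse number occurs in 1 group only.

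Most directions held, while calls and counts moved. For named genes that passed, 1212 values under other settings gave 0 reversals and 159 losses of the call, and 1390 values with 1 array left out gave 0 and 509. Many of the 1212 values could not reverse. Other filters, variance models and choices of probe sets, and a fit to the compared groups alone, leave the log2 value of a probe set unchanged. For named genes, these settings therefore test the call and not the direction. For gene lists called by camera, 486 values gave 2 reversals and 121 losses, and 540 with 1 array left out gave 0 and 82. Most of the 121 losses came from the other list tests. Of 36 list calls, 0 were kept with an estimated correlation, 4 by exact permutation and 8 by fry. The most lost under any other setting was 8, without both arrays with the most empty cells. With an estimated correlation no reversal was possible, since the main direction was reused. Among genes and lists not called, 20 of 1491, 6 of 1520, 34 of 2146 and 58 of 2260 values became calls and 2 of the 2146 reversed. The reversals were oxidative phosphorylation for the transgene under quantile normalization (0.063 log2 in trained mice, 0.028 averaged over training) and, with array weights, fatty acid uptake and oxidation for training in wild-type mice (median 0.036) and the interaction (median 0.10), where camera's direction turned. The cause was not tested.

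Counts of called probe sets that moved by more than 1.5 times follow; the cause was not tested. For training in transgenic mice (42), the count was 153 under quantile normalization, 11 with arrays centred on their medians, 69 with an added constant of 1, 6 without a filter and 99 with a filter at the 60th percentile. It was 65 without a variance trend, 67 with robust variances, 1 (limma) with the compared groups alone, 2 without probe sets that can bind several transcripts and 24 with 1 probe set per gene. It was 125 without both arrays with the most empty cells, 72 without probe sets with an empty cell and 371 with the Gapdh covariate. For the transgene in untrained mice (15), it was 0 by limma with the compared groups alone and 48 with the Gapdh covariate. For the transgene in trained mice (7), it was 13 with the 60th percentile filter, 26 with the compared groups alone, 3 without probe sets that can bind several transcripts, 4 with 1 probe set per gene, 12 without both arrays and 19 with the Gapdh covariate. For training averaged (678), it was 409 with centring, 448 without a filter, 335 without probe sets that can bind several transcripts, 409 without both arrays and 1292 with the Gapdh covariate. For the transgene averaged (167), it was 111, 89 and 102 without a filter, without such probe sets and with 1 per gene, 399 without both arrays and 464 with the Gapdh covariate. Array weights gave 92, 2467, 94 and 1016 for the single contrasts in the order of training in wild-type and transgenic mice and the transgene in untrained and trained mice, 7 for the interaction, 2771 for training and 662 for the transgene averaged.

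With 1 array left out, counts ran from 0 to 4 for training in wild-type mice, 2 to 764 in transgenic mice, 2 to 26 and 2 to 1.4e+02 (13 higher and 90.8% lower at the upper end) for the transgene in untrained and trained mice, 279 to 1285 for training and 79 to 525 for the transgene averaged. The interaction stayed at 0 by limma in all 20 fits (395 at an unadjusted p under 0.05 with all arrays). Calls that failed in more than 10 of those 20 fits were, for training, those of Col3a1, Tfrc, Mybph, Snhg1, Xbp1, Atf4, Mpeg1, Plin4, Ucp3, Phkb, Eif4ebp1, Foxo3 and Cs, and for the transgene those of Ctsc, Car14, Atf4 and Thbs4. Dim genes such as Tap1 (79.4 intensity) lie below the filter, where signal over background limits any statement.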

Other observations

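The clock score and the glucocorticoid score were chosen only after the result was seen.

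Among the clock genes examined, Arntl passed the threshold for training and Tef for the transgene, and the circadian clock list of 12 genes was not called (median -0.06 log2 for training, camera adjusted p = 0.587, exact permutation p = 0.219; 0.05 for the transgene, camera adjusted p = 0.229, exact permutation p = 0.334). Arntl, the clock's core activator, stood at 345 ± 147.1 intensity (SD, n = 5) in untrained and 192 ± 123 in trained wild-type mice, and at 249 ± 68 and 97.2 ± 39.2 in transgenic mice, and fell with training by 0.84 ± 0.20 on the log2 scale (adjusted p = 0.025). That call was lost without TGT-128, TGUT-131 or WTUT-135 (adjusted p of at most 0.054). Clock, the other activator measured, had values of -0.04 for training and 0.05 for the transgene. Among output genes of the opposite phase, training values were 0.71 ± 0.31 log2 for Dbp (adjusted p = 0.206), 0.34 for Nr1d2, 0.10 for Tef, -0.12 for Nr1d1 and -0.03 for Per3, and transgene values were 0.97 ± 0.31 for Dbp (adjusted p = 0.124), 0.31 for Nr1d2, 0.34 ± 0.06 for Tef (adjusted p = 0.00581), 0.06 for Nr1d1 and 0.06 for Per3. A score of activators minus output genes, from 2 of 3 and 5 of 7 listed genes that were measured, averaged 0.59 ± 0.21 and -0.04 ± 0.53 in untrained and trained wild-type mice and 0.06 ± 0.42 and -0.60 ± 0.34 in transgenic mice. It differed by -0.64 for training averaged over genotypes (exact permutation p = 0.00183, adjusted 0.0128 over 7 contrasts) and by -0.55 for the transgene averaged over training (exact permutation p = 0.00579, adjusted 0.0203). The interaction was -0.03 (exact permutation p = 0.943). The labels give no time of sampling.

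No contrast of the glucocorticoid and fasting score passed the correction over 7 contrasts. The score differed by -0.38 for training averaged over genotypes (exact permutation p = 0.0157, adjusted 0.0556), by -0.63 for training in transgenic mice (exact permutation p = 0.0159, adjusted 0.0556), by -0.14 in wild-type mice (exact permutation p = 0.54) and by -0.45 for the transgene in trained mice (exact permutation p = 0.0556, adjusted 0.13), and the training response was not shown to differ between genotypes (interaction -0.49, exact permutation p = 0.135). Averaged over genotypes, Klf9, a transcription factor induced by glucocorticoids, fell by 0.41 ± 0.11 on the log2 scale (adjusted p = 0.0341), and the chaperone Fkbp5 had a value of -0.43 ± 0.19 (adjusted p = 0.196).

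The inducible Hsp70 gene Hspa1b had a large but variable difference in untrained mice, -2.70 ± 0.77 log2 for the transgene (adjusted p = 0.254).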
